A study of Homo sapiens with 2 samples.

How the data were processed

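Gene expression was measured in 2 stable clones of TMK-1, a human gastric adenocarcinoma cell line, with 1 array per clone. The control clone, numbered 4 in the labels, expressed a microRNA-type hairpin with a non-targeting sequence. The knockdown clone, numbered 1, expressed a hairpin directed against nardilysin (NRDC, older symbol NRD1). Per the labels' protocols, both clones were selected with an antibiotic marker carried by the vector. Total RNA was column-purified and treated with DNase, and 100 ng was converted to biotinylated sense-strand DNA for an Affymetrix whole-transcript array, per the labels' protocols.

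The deposited table holds 1 log2 signal per probe set and array, for 28869 probe sets. The program that summarised the probes, the background correction, the normalization and any constant added before the log2 step are not given in the sources used here. The log2 scale was inferred from the deposited values, which run from 4.18 to 14.51 on the control array and from 4.19 to 14.38 on the knockdown array. No value lies below 4, and 10.6% of probe sets on each array lie below 4.5. Values thus pile up at the low end of the scale, and fold differences of genes with a signal close to it may be understated. The array medians were 6.03 and 6.01, and 737 probe sets (2.55%) carried the identical value on both arrays. Arrays give no counts, so the precision of every value is limited by the number of arrays, which is 1 per group.

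Probe sets were named through the platform's annotation table: 19310 had 1 gene symbol, 1752 had several and 7807 had none. Of the 19310, 19279 matched the RefSeq gene table of assembly GRCh38.p14 by gene identifier, and no symbol needed an update. The build behind the array's design is not given in the sources used here, so no coordinates are printed and the RefSeq table served only for names and for the order of genes along chromosomes. Probe sets with several symbols were left out of the comparison. Where a gene had several probe sets (685 genes), the one with the highest mean over the 2 arrays was used. This left 18377 named genes. An expression floor then kept the 9543 genes at or above the median of all named genes on at least 1 array (6.68 on the control array, 6.70 on the knockdown array). The array medians differed by less than 0.1, so values were used as deposited, without further scaling.

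The comparison was the log2 signal of the knockdown clone minus that of the control clone. With 1 array per group no test between conditions is possible: there is no estimate of the spread between samples, no standard error and no p-value, and no difference below has a replicate check. Genes were described by a size rule, at least 2-fold for counts over all genes and at least 1.5-fold for members of gene lists. The only spread that the table offers is technical: in the 293 genes with several probe sets past the floor, the log2 differences of probe sets of the same gene had a pooled SD of 0.13. This figure is lowered by 92 genes whose probe sets had an SD under 0.01 and may be near-duplicates. Without them the pooled SD was 0.15, and the largest SD was 0.80, for GLUL.

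The 32 gene lists, the rule for named genes, the alternatives and the size thresholds were fixed before the data were examined. The rule named NRDC, the 15 highest and 15 lowest log2 differences past the floor (leaving out small RNAs, uncharacterised loci and receptor families by symbol), and in each list up to 2 members per direction that differed at least 1.5-fold. For each list with 5 or more members past the floor, the median log2 difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its percentile was under 2.5 or above 97.5. This describes these 2 arrays and is not a test between conditions. Some genes belong to several lists. Genes named beyond the rule were chosen after their values were seen: other M16 and sheddase members, members of lists with too few genes past the floor, 5 interferon-stimulated genes, 3 cytokines and TNF, SREBF2, ATF4, ZEB1 and a probe set shared by HLA genes.

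Alternatives were median centring, quantile normalization, subtraction of a lowess trend (fraction 0.3, 3 iterations), the mean over a gene's probe sets, no floor, a floor at percentile 75, a 1.5-fold threshold, probe sets with several symbols kept, the mean of a list in place of its median, and unmatched random lists. A pseudocount on linear values did not apply, since the deposited values are already on the log2 scale. A planned search for matches to the hairpin's seed in 3' untranslated regions was not run, because no transcript sequences were used here. Subtraction of the running median of the 40 nearest genes along the chromosome was added after seeing the data, as were the M16 list without NRDC and a search for runs of neighbours on alternate genes, measured on the genes left out.

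The list procedure was tested on simulated differences for the 9543 genes, with normal noise at the robust SD of the observed differences (0.24), which holds no separate spread between clones. The noise was drawn independently for each gene, whereas genes of a fixed list may vary together. The procedure placed 4% of unchanged lists of 20 genes outside the central 95%, 89% of lists shifted by 0.2 and 100% of lists shifted by 0.5 on the log2 scale. For the 2-fold counts, 5% of simulated genes with a 1.5-fold change, 51% with a 2-fold change and 99% with a 3-fold change were counted. The simulated noise had the same SD for every gene. Observed log2 differences had an SD of 0.59 in the dimmest decile and 0.26 in the brightest, so these rates may not hold for dim genes. The simulation says nothing about 2-fold differences that arise between clones without any knockdown. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.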

Results

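Genome-wide expression was profiled in 2 stable clones of the gastric adenocarcinoma line TMK-1, to ask which transcripts differ when nardilysin is lowered by RNA interference. Nardilysin (NRDC) is a metallopeptidase of the M16 family that cleaves at dibasic sites and is known to promote ectodomain shedding by ADAM proteases. Each group held 1 clone and 1 array: a control clone with a non-targeting hairpin, and a knockdown clone whose hairpin was directed at the 21-nucleotide sequence CTGATGCAAACAGAAAGGAAA. The genomic position of this target was not determined here. The 2 arrays had median log2 signals of 6.03 and 6.01. All differences below are between these 2 clones, without replicates.

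NRDC was lower in the knockdown clone. Its log2 signal was 10.57 in the control clone and 9.01 in the knockdown clone, a 2.93-fold difference that left 34.1% of the control signal. This was the 21st lowest log2 difference among the 9543 genes past the expression floor, so 20 other genes were lower by more. Among other members of the M16 family, chosen after their values were seen, log2 differences were -0.09 for IDE (insulin-degrading enzyme), 0.37 for PITRM1 and -0.07 for UQCRC1. The list of M16 metallopeptidases and dibasic convertases had NRDC as its only member of 10 beyond 1.5-fold, and its median of -0.08 lay at percentile 8.29 of random lists. Its mean of -0.17 lay at percentile 1.65 of random means, and without NRDC the mean of the other 9 was -0.013, at percentile 28.8.

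More genes were at least 2-fold higher than lower in the knockdown clone. Of the 9543 genes, 169 were at least 2-fold higher in the knockdown clone and 61 at least 2-fold lower, together 2.41%. At 4-fold, 38 genes were higher and 12 lower. In all, 93.3% of the 9543 genes lay within 1.5-fold, the SD of log2 differences was 0.38, and Pearson's r between the arrays across genes was 0.96. Genes are not independent replicates, and this r describes only the pair of arrays. Of the 169 higher genes, 93 lay below the floor on the control array, and of the 61 lower genes, 40 lay below it on the knockdown array. Those with a signal close to the low end of the scale may have understated fold differences. Selection by size on 1 pair of arrays can also overstate differences, and no replicate shows which applies. Log2 differences had an SD of 0.59 in the dimmest decile of the 9543 genes by mean signal and 0.26 in the brightest.

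**Figure D1:**
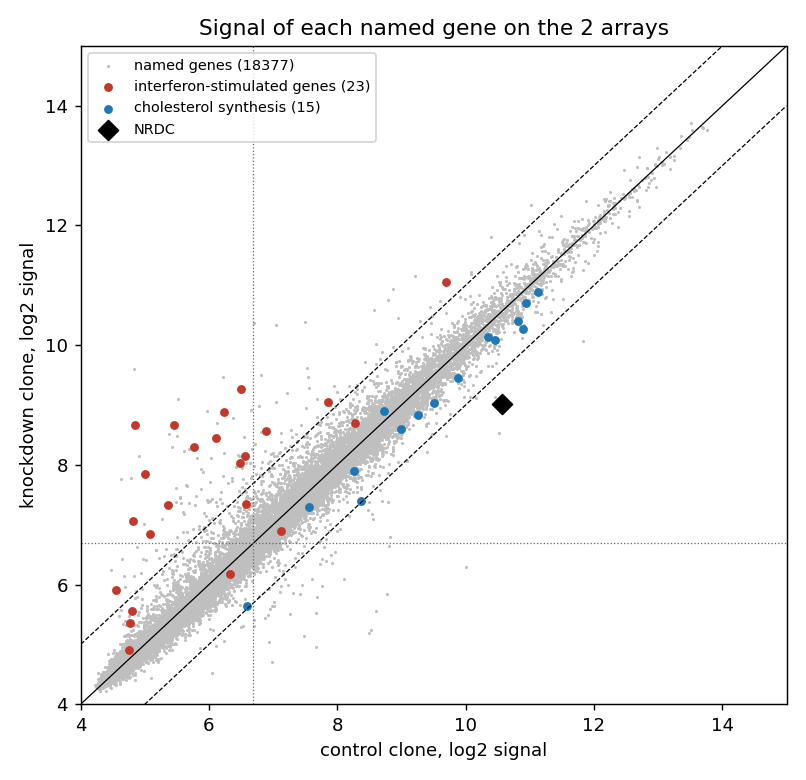
Log2 signal of 18377 named genes in the control clone (x axis) and the knockdown clone (y axis), 1 array each. The solid line marks equal signal, dashed lines 2-fold differences and dotted lines the expression floor. NRDC lies below the lower dashed line at 10.57 and 9.01, and 16 of the 18 interferon-stimulated genes past the floor lie at least 1.5-fold above equal signal. Red points are interferon-stimulated genes and blue points are cholesterol synthesis genes.

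SLC6A14, an amino acid transporter, had the highest log2 difference in favour of the knockdown clone and was 27.1-fold higher (log2 signal 4.84 against 9.60). IFIT1 and MX1, antiviral proteins induced by interferon, were 14.2-fold and 9.29-fold higher, and DDX60 and SAMD9, also known as interferon-inducible, were 8.01-fold and 7.33-fold higher. KLK5, a secreted serine protease of the kallikrein family, was 12.8-fold higher, and PSCA, a GPI-anchored surface antigen of gastric and prostate epithelium, was 7.45-fold higher. BPIFB1, a secreted airway and mucosal protein, was 7.88-fold higher, and MUCL1, a small mucin-like protein, was 9.60-fold higher. MATN2, a matrix adaptor protein, had a log2 signal of 5.52 in the control clone and 9.10 in the knockdown clone. It lies in a run of 38 neighbouring genes along the chromosome whose median log2 difference was 0.28. GLUL, glutamine synthetase, was 9.85-fold higher by the brighter of its probe sets, a log2 difference of 3.30, while its other probe set gave 2.17. Which transcripts each of these probe sets measures was not checked, so the size of the GLUL difference and its place among the 15 highest are uncertain. QPCT, a glutaminyl cyclase, was 9.41-fold higher, CHN1, a Rac GTPase-activating protein, 8.86-fold, PLAAT4, a phospholipase and acyltransferase inducible by retinoids, 8.80-fold, and BCAS1 7.65-fold. KLK5, GLUL and PSCA were past the floor in both clones, though KLK5 only just in the control clone (6.70 against a floor of 6.68). The control signals of the other 12 of these 15 genes lay below it.

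Of the lower genes, PPDPFL was 13.1-fold lower (10.00 against 6.29), and CP, the copper-binding plasma protein ceruloplasmin, was 9.79-fold lower. UNC13A, a synaptic vesicle priming factor, was 9.75-fold lower, KCNMB4, a potassium channel subunit, 7.58-fold, TRPA1, a cation channel, 5.08-fold, and DPYSL2 4.09-fold. CCNA1, a cyclin known from the germ line, was 8.26-fold lower, and UGT8, which makes galactosylceramide, 6.57-fold lower. SERPINE2, an inhibitor of secreted serine proteases, was 4.89-fold lower, and CXCL5, a neutrophil chemokine, was 4.52-fold lower. MSC, a bHLH repressor, was 4.42-fold lower, STC1, a secreted glycoprotein, 4.01-fold, WFDC1, a secreted protein with a protease inhibitor fold, 3.95-fold, and GNAI1 and CALB2 each 3.72-fold. WFDC1 and DPYSL2 were past the floor in both clones.

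**Figure D2:**
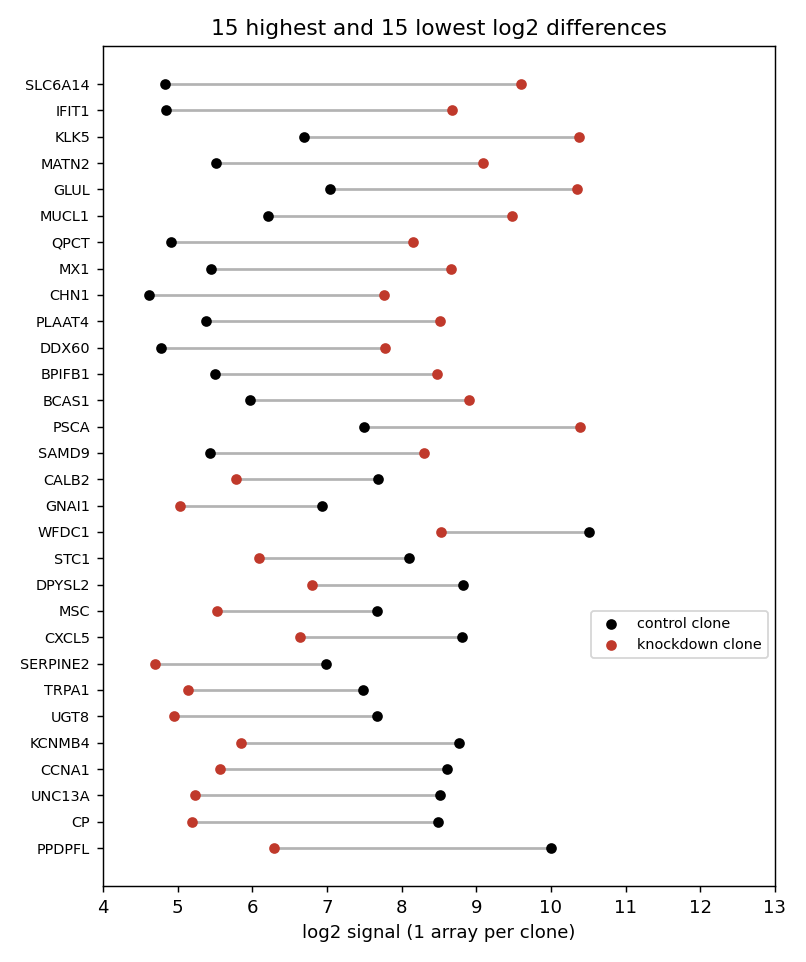
Log2 signal (x axis) of the 15 genes with the highest and the 15 with the lowest log2 difference past the expression floor (y axis), with 1 black point for the control clone and 1 red point for the knockdown clone. The widest gap is that of SLC6A14, from 4.84 to 9.60.

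Of the 27 fixed gene lists with 5 or more members past the floor, 10 stood apart from matched random lists, 6 with a higher and 4 with a lower median in the knockdown clone. Lists of genes drawn at random would give 1.35. Genes of a fixed list may vary together, so more than 1.35 can stand apart between 2 clones without any knockdown. The widest shift was that of interferon-stimulated genes, of which 23 were measured and 18 were past the floor. Of these 18, 16 were at least 1.5-fold higher and none was 1.5-fold lower. The median log2 difference was 1.87, above each of the 10000 random lists. Most of the 18, IFIT1 and MX1 among them, passed the floor only on the knockdown array, which can raise the count and median. Members below the floor in both clones had log2 differences from -0.16 to 1.36, and the list also stood apart without the floor. Besides IFIT1 and MX1, the higher members included OAS2, which activates RNase L on double-stranded RNA (6.84-fold higher), IFIH1, a sensor of double-stranded RNA (4.75-fold), and IRF9, a subunit of the transcription factor complex ISGF3 (2.98-fold). Of the 18, only MX2 (log2 difference 0.42) and IRF7 (-0.22) lay within 1.5-fold. These 5 were named after their values were seen.

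Genes of MHC class I antigen presentation were higher as well. All 9 measured members had a positive log2 difference, 5 were at least 1.5-fold higher, and the median was 0.65, above each of the random lists. PSMB9 and PSMB8, subunits of the immunoproteasome, were 3.27-fold and 2.66-fold higher. These genes are themselves known to respond to interferon, and no HLA gene was among the 9 measured members. In a probe set with several symbols, shared by HLA-B and HLA-C and chosen after its values were seen, the log2 signal was 10.20 in the control clone and 11.20 in the knockdown clone. Markers of immune cells had a median log2 signal of 5.26 in the control clone and 5.17 in the knockdown clone, with 2 of 14 past the floor, and markers of fibroblasts and endothelium had medians of 5.36 and 5.29. Markers of hepatocytes and neuroendocrine cells had medians of 5.65 and 5.69. CD14, a monocyte co-receptor, was the only member of these 3 lists beyond 1.5-fold, with a log2 difference of -0.69.

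Epithelial junction and keratin genes stood apart on the higher side. Of 22 members, 8 were at least 1.5-fold higher and none 1.5-fold lower, 21 had a positive log2 difference, and the median was 0.51, above each of the random lists. KRT19, a keratin of simple epithelia, was 2.52-fold higher and RAB25, an epithelial trafficking GTPase, was 2.30-fold higher. Mesenchymal genes and EMT factors did not stand apart, with a median of -0.03 at percentile 32.8 over the 8 of 19 measured members past the floor. Of those below the floor only ZEB1, an EMT factor named after its values were seen, was beyond 1.5-fold. It was 2.29-fold lower in the knockdown clone (6.49 against 5.30). In that list SPARC, a matrix glycoprotein, was 2.57-fold lower and TAGLN, an actin-binding protein, 2.15-fold higher. Gastric mucosa markers had a median of 0.32 over 6 members, at percentile 99.0, with the trefoil peptides TFF2 and TFF1 2.75-fold and 2.67-fold higher. Without the floor this median was 0.028, inside the central 95%. The other 4 lay within 1.5-fold, and 10 further measured markers were below the floor. Of the intestinal markers only 4 were past the floor, and TFF3 was the only one beyond 1.5-fold, with a log2 difference of 0.87.

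Cholesterol synthesis genes were lower in the knockdown clone. The median log2 difference over 14 members was -0.37, below each of the random lists, and 13 of the 14 were negative. INSIG1, a sterol-responsive regulator of the pathway, was 1.97-fold lower and HMGCS1, HMG-CoA synthase, was 1.54-fold lower, while the other 12 lay within 1.5-fold. SREBF2, a transcription factor of the pathway named after its values were seen, had a log2 difference of -0.43 and lies in a run of 101 neighbouring genes whose median was -0.30. Genes of the unfolded protein response and integrated stress response had a median of -0.21 over 19 members, also below each of the random lists. Their mean was smaller, at -0.11, and the list stood apart under every alternative. Here 12 members were negative and 7 positive: ASNS, asparagine synthetase, was 1.53-fold lower, SDF2L1, an endoplasmic reticulum chaperone component, had a log2 difference of -0.59, and DDIT3, the stress transcription factor CHOP, was 1.90-fold higher. SDF2L1 lies in a run of 34 neighbouring genes along the chromosome whose median log2 difference was -0.28. After the running median of neighbours was subtracted, its log2 difference was -0.38, within 1.5-fold. ATF4, a transcription factor of the stress response named after its values were seen, had a log2 difference of -0.14 and lies in the same run as SREBF2.

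Genes of the mitotic apparatus were slightly lower, with no member of 24 beyond 1.5-fold, 19 negative values and a median of -0.12 at percentile 0.19. The DNA replication and S phase list had a median of -0.06 at percentile 4.23, inside the central 95%, while its mean of -0.080 lay at percentile 1.87. Its only member beyond 1.5-fold was CDC45, a replicative helicase subunit, 1.91-fold lower, which lies in the same run of neighbours as SDF2L1.

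Of 16 NF-kB feedback and response genes, none was 1.5-fold lower and 1, CYLD, a deubiquitinase, was 1.62-fold higher. Their median was -0.12 at percentile 1.91, and this lay inside the central 95% without the floor (-0.069) or when the mean was taken (-0.092). Inflammatory cytokines and chemokines had 5 of 14 members at least 1.5-fold lower and 2 at least 1.5-fold higher, and their median of -0.07 lay at percentile 18.4. The lower 5 were CXCL5, IL1A (2.69-fold), IL6 (2.64-fold), CXCL8 (1.97-fold) and CXCL1 (1.60-fold), of which IL6, CXCL8 and CXCL1 were named after their values were seen. The higher 2 were CSF1 (2.22-fold), a macrophage growth factor, and CCL5 (2.11-fold), a chemokine also known to be inducible by interferon. The mean of the 14 members was -0.31, at percentile 0.28 of random means, and without the floor the list's median was -0.11, at percentile 1.15. TNF itself, also chosen after its values were seen, was below the floor in both clones, at 6.49 and 6.31.

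STAT3 targets and IL-6 family receptors had a median of 0.02 and a mean of -0.08, with FGB, fibrinogen beta chain, 3.39-fold lower and BCL6 1.54-fold higher among 17 members. In the EGFR family list, the ligands EPGN (epigen) and EREG (epiregulin) were 2.72-fold and 2.01-fold lower, and the median over 8 members was -0.07 at percentile 19.9. ERK feedback and immediate-early genes had a median of -0.09 at percentile 10.4, with the ETS factors ETV5 and ETV4 2.21-fold and 1.89-fold lower and JUN 2.36-fold higher. Without the floor that median was -0.13, at percentile 1.75. Sheddases and their regulators stood apart on the higher side, with a median of 0.22 over 11 members at percentile 99.2. Of these, 8 were positive and 3 negative. The list pools proteases with TIMP inhibitors, so its median gives no direction for shedding. The 2 beyond 1.5-fold were BACE2, an aspartyl protease (1.97-fold), and TIMP2, a metalloprotease inhibitor (1.75-fold), and ADAM17 and ADAM10, chosen after their values were seen, had log2 differences of -0.13 and 0.20. The list of TGF-beta and Hippo/YAP targets had a median of 0.24 over 12 members at percentile 99.1. It also holds TGF-beta ligands and a receptor, so its median is not a readout of target genes alone. Of the 12 members, 8 were positive, 4 negative and 10 within 1.5-fold. The 2 beyond it were ID2 and ID3, inhibitors of bHLH factors, 2.40-fold and 1.62-fold higher. ID3 lies in a run of 36 neighbouring genes whose median log2 difference was 0.25. After the running median of neighbours was subtracted, the log2 difference of ID3 fell from 0.70 to 0.45, within 1.5-fold. Without the expression floor, the sheddase median was 0.053, inside the central 95%. With the mean in place of the median, the sheddase list (0.23) and the TGF-beta and YAP list (0.25) also lay inside it, as did the TGF-beta and YAP median with the floor at percentile 75.

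The remaining lists did not stand apart. The p53 targets had a median of 0.14 at percentile 92.1, with TP53INP1 2.59-fold higher and SESN1 1.53-fold lower. Apoptosis regulators had a median of 0.04, with the death ligand TNFSF10 1.66-fold higher. Heat shock genes had a median of 0.09, with HSPB1 1.93-fold higher, and hypoxia and glycolysis genes likewise 0.09, with ALDOC 1.78-fold lower. The PGC-1alpha and lipid oxidation list had a median of -0.08, with PPARA 1.84-fold lower, and PPARA lies in a run of 101 neighbouring genes whose median log2 difference was -0.30. Wnt and stem cell genes had a median of -0.01 and a mean of 0.13, with ALDH1A1 1.70-fold higher. MicroRNA biogenesis genes (median -0.08), cytosolic ribosomal proteins (median -0.005, mean 0.01) and the nuclear-encoded respiratory chain (median -0.02, mean 0.01) had no member beyond 1.5-fold. Reference housekeeping genes had a median of -0.04 and a mean of 0.01, and B2M, which also belongs to the antigen presentation list, was the only one beyond 1.5-fold at 1.57-fold higher. Of the matrix metalloproteinase and plasminogen activation list only 4 members were past the floor: SERPINE2, MMP15 (log2 difference -0.51), PLAUR (0.46) and PLAU (1.04).

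**Figure D3:**
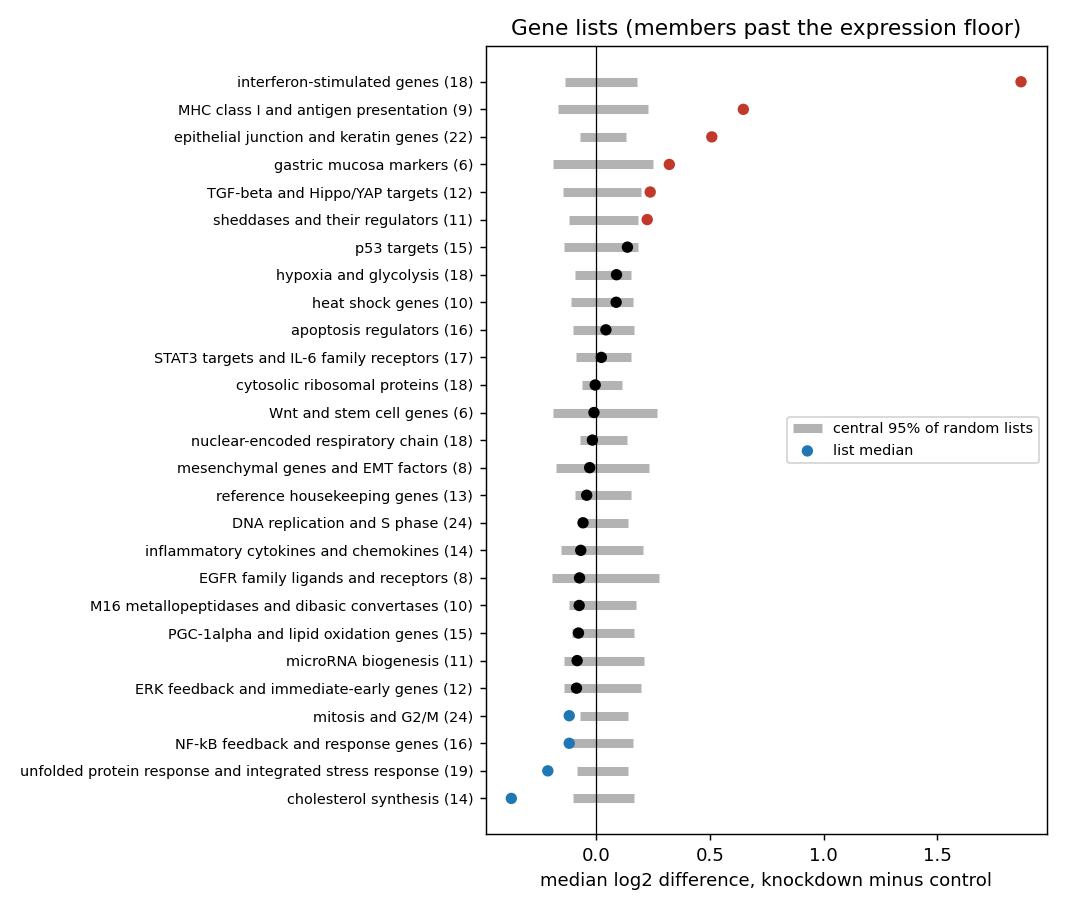
Median log2 difference, knockdown minus control (x axis), of the 27 gene lists with 5 or more members past the expression floor (y axis, number of members in parentheses). Points are the list medians, red above, blue below and black inside the grey bars, which span the central 95% of 10000 matched random lists. Interferon-stimulated genes lie farthest to the right at 1.87 and cholesterol synthesis farthest to the left at -0.37.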

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

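The test of immune cell markers, the list of interferon ligands and the subtraction of neighbouring genes were chosen only after the main results were seen.

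Probe sets outside the comparison also held signal. Among probe sets with several gene symbols, 5 were at least 2-fold higher on the knockdown array, led by one shared by TLCD4 and its readthrough transcript (log2 difference 3.35), one shared by OCLN, the tight junction protein occludin, and its pseudogene (3.06), and one shared by USP18 and its pseudogene (2.09). Another 5 were at least 2-fold lower, with the probe set of the UGT1A family at -2.09. Among probe sets with no gene symbol, 11 were at least 2-fold higher and 2 at least 2-fold lower.

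The pattern most in need of follow-up is the higher signal of interferon-stimulated genes in the knockdown clone. An intensity-dependent scaling difference is argued against, since the list's median was 1.92 after the lowess trend was subtracted. Immune cells in the culture are not excluded: the median log2 difference of 14 immune markers was -0.067, but only CD14 (-0.69) and CD68 (0.43) were past the floor and they went opposite ways. Interferon made by the cells themselves stays open: 0 of 13 measured interferon ligand genes were past the floor and 1.5-fold higher, but only IFNL3 was past the floor at all. With 1 clone per group, loss of nardilysin, another effect of the hairpin or vector and a difference between the clones cannot be told apart. The control clone also carried a hairpin, with a non-targeting sequence.

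The lower medians of the cholesterol synthesis list and of the unfolded protein response and integrated stress response list form another pattern. In the second list the members were mixed: 16 of 19 lay within 1.5-fold, 12 were negative and 7 positive. Intensity-dependent scaling is argued against, because the cholesterol median was -0.39 and the other list also stayed under the 2.5th percentile after the lowess trend was subtracted. A regional copy number difference acting on the lists' own genes is argued against as the whole cause: 1 of 14 cholesterol and 2 of 19 stress response genes lie in the runs of neighbouring genes described under the other observations, and after subtraction of the running median of 40 neighbours the medians were -0.33 and -0.13, at percentiles 0.00 and 1.02. That subtraction cannot show an indirect effect, which stays open: SREBF2, a transcription factor of cholesterol synthesis (log2 difference -0.43, or -0.14 after subtraction), and ATF4, one of the stress response (-0.14 before, 0.15 after), lie in the longest lower run. A different growth state of the cultures at harvest also stays open, since there was 1 harvest per group, and so does an effect of nardilysin, which is untested.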

How the results depend on the processing

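The comparison has 1 array per group, so no array could be left out, no split of the samples exists and no p-value can be given. No paired analysis was possible because each group holds 1 array. NRDC had a log2 difference between -1.59 and -1.53 under the scalings and the subtraction of neighbours. A change of the floor cannot move a single gene, nor can the mean over probe sets where a gene has 1. The scalings moved none of the 68 named genes by more than 0.053. GLUL moved to 2.73 with the mean over probe sets, and 9 named genes moved by more than the probe set SD of 0.13 under the subtraction of neighbours. The 2-fold counts of 169 higher and 61 lower stayed within 1.5 times under every scaling, without the floor and with probe sets of several symbols kept. They were 78 and 22 with the floor at percentile 75, which tests fewer genes, and 473 and 171 at 1.5-fold. The share of higher genes among 2-fold genes lay between 70.7% and 78.0%, and no scaling moved the median of all genes past the floor beyond 0.05. Interferon-stimulated (1.57 to 2.44), antigen presentation (0.54 to 0.75), epithelial (0.47 to 0.54), cholesterol synthesis (-0.42 to -0.33), stress response (-0.22 to -0.11) and mitotic (-0.16 to -0.10) lists stood apart under every alternative. Without the floor, the NF-kB (-0.069), sheddase (0.053) and gastric marker (0.028) lists no longer stood apart, whereas the cytokine (-0.11) and ERK (-0.13) lists did. With the mean, the NF-kB (-0.092), sheddase (0.23) and TGF-beta and YAP (0.25) lists no longer stood apart, whereas the cytokine (-0.31), M16 (-0.17) and DNA replication (-0.080) lists did. The TGF-beta and YAP list (0.24) also lost its place with the floor at percentile 75. Under the subtraction of neighbours, which was chosen after seeing the data, NF-kB (-0.12) no longer stood apart and ERK (-0.19) and DNA replication (-0.09) did. The cytokine median was 0.19 with the floor at percentile 75, inside the central 95%. The M16 mean rests on NRDC itself: without the targeted gene, a setting chosen after seeing the data, the mean of the other 9 was -0.013, at percentile 28.8. The causes of the other changes were not tested. The planned pseudocount and seed match alternatives were not run.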

Other observations

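The gene groups, the runs and the tests on held-out genes in the longest run were chosen only after the data were seen. The gene groups hold the genes that prompted them, among them SAMD9, IFIH1, IRF9, KLK5, BPIFB1, CP and FGB, so their counts and medians are not independent of the differences already described. The floor keeps a gene that is high in either clone, so some members entered only through the clone where they are high.

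Further antiviral genes were higher in the knockdown clone. Of 15 measured tripartite motif, PARP and related antiviral genes, 11 were past the floor. Of these 11, 6 were at least 1.5-fold higher and none lower, with PARP9 3.94-fold and DTX3L 2.18-fold higher. Of 6 sensors of double-stranded RNA, 3 were at least 1.5-fold higher, namely IFIH1 and RIGI (3.23-fold), which also belong to the interferon-stimulated list, and EIF2AK2 (1.81-fold). In contrast, 12 genes of interferon receptors and signalling had a median of -0.11, and only IRF9 was beyond 1.5-fold. None of 10 measured interferon-gamma-type targets was past the floor, with CXCL10 at 4.73 in the control and 4.99 in the knockdown clone, and GBP3, the only one beyond 1.5-fold, at 4.70 and 5.38. The antigen presentation genes described above, which also respond to interferon and were higher, are not in this group. It therefore does not exclude a response of the interferon-gamma type.

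Of 17 measured mucosal defence genes, 7 were past the floor. Of these, 4 were at least 1.5-fold higher: BPIFB1, PLA2G2A (4.61-fold), a secreted phospholipase, DEFB1 (1.93-fold) and LCN2 (1.61-fold). PI3, an elastase inhibitor, was 1.77-fold lower. BPIFB1 and DEFB1 passed the floor only on the knockdown array, and the measured genes below it all lay within 1.5-fold. PLA2G2A lies in one of the runs of higher neighbouring genes, and its log2 difference of 2.21 was 1.96 after the running median was subtracted. Acute phase proteins had a median of -0.72 over 8 members: CP, FGB, ORM1 (2.15-fold), ORM2 and C3 (1.67-fold) were at least 1.5-fold lower and CFB was 1.56-fold higher. The calgranulins S100A8 and S100A9 were 2.66-fold and 1.58-fold lower and S100A14 was 1.84-fold higher, while the S100 list as a whole had a median of -0.002. Of 12 kallikreins only KLK5 and KLK10 (log2 difference 0.06) were past the floor, and KLK6, at 5.92 and 6.63, was 1.64-fold higher below it. Of 6 stratified epithelial keratins, KRT4 (6.47-fold) and KRT80 (2.18-fold) were beyond 1.5-fold and the median was 0.23. Epithelial transcription factors had a median of 0.16 over 7 members, with EHF 6.13-fold and ELF3 1.84-fold higher. Replication-dependent histone genes had a median of -0.34 over 40 members, 36 of them negative, while H4C8 was 2.82-fold higher. Their probe sets measure near-identical copies, so single histone genes are uncertain, the members are not independent values and no percentile is given.

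Neighbouring genes shifted together in 5 runs of 20 or more genes whose 41-gene window medians lay outside the range of 100 shuffles of the gene order (-0.18 to 0.24). The longest ran from APOL2 to CERK, where 92 of 101 genes were lower in the knockdown clone, with a median of -0.30, or 81.2% of control. A run on the same chromosome from UFD1 to GUSBP11 (34 genes, median -0.28) and one from TWSG1 to GALNT1 (45 genes, median -0.23) were lower, and runs from PLEKHF2 to SYBU (38 genes, median 0.28) and from MICOS10 to SRSF10 (36 genes, median 0.25) were higher. The share of lower genes in a run is raised by the way runs were found, so runs were also searched on alternate genes and measured on the genes left out, both ways round. The longest lower run then went from MAFF to KIAA0930 1 way round and from ZC3H7B to CELSR1 the other, both inside APOL2 to CERK. The outer parts of APOL2 to CERK were not checked in this way. Inside the shorter runs, 28 of 29 and 20 of 21 held-out genes were lower. The lower share was 95.2% (95% exact interval 76.2% to 99.9%, which treats genes as independent), so a few co-regulated neighbours are argued against there. Gene density is argued against, since 2027 other windows packed as densely had a median of 0.0335. A candidate explanation is a regional copy number difference between the clones, and a regional chromatin difference is another. No value here decides between them: the dimmer held-out genes had medians of -0.22 and -0.27 and the brighter ones -0.30 and -0.43, but with so few held-out genes above 0 no median could lie above 0, and no DNA was measured.

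Of the 230 genes beyond 2-fold, 6 lie in these runs, and subtraction of the running median gave 159 higher and 63 lower genes. With the lowess trend subtracted, an alternative fixed in advance, 167 genes were higher and 61 lower. MATN2 (3.58 before, 3.27 after), CDC45 (-0.94, -0.63), PPARA (-0.88, -0.66), ID3 (0.70, 0.45) and SDF2L1 (-0.59, -0.38) are the genes named by the fixed rule that lie in the runs, with log2 differences before and after that subtraction of neighbours.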
